A study of Mus musculus with 2 samples.

How the data were processed

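Single cells carrying the Ctsk-Cre reporter were profiled from the femurs of 2 C57/B6 mice of the same litter on postnatal day 6. In this genotype Cre is made under the cathepsin K (Ctsk) promoter, and a cell in which Cre has acted makes membrane-bound GFP, so the sorted cells are those with present or past Ctsk promoter activity and their descendants. Femurs were digested, stained with antibodies and sorted as single GFP-positive cells into plates, 1 plate per animal (plate 47 for animal 1 and plate 48 for animal 2). Complementary DNA was made in each well by template switching and amplified by PCR, then pooled, and libraries were prepared with Nextera XT and sequenced on an Illumina HiSeq instrument. Well names give a plate quadrant and a well barcode. Because each animal filled its own plate, animal and plate cannot be told apart.

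The values are those of the deposited table, whole-number counts per gene and well for 24866 genes and 658 wells, which the authors made against build mm10 with CASAVA per the labels. The aligner, the counting tool, the gene annotation, any filter on wells and any collapsing of duplicate reads are not given in the sources used here. A count was not read as 1 molecule: a gene detected in a cell had a median of 18 counts, 23.1% of nonzero values were 1, and the median variance-to-mean ratio of 1695 low genes was 24.8. The plan, written before the data were examined, spoke of molecular identifiers, and its minimums were applied to these counts. Binomial intervals are exact (Clopper-Pearson, 95%) and, like the limit of 3 counts that a 0 allows, cover counting error only. The table held no gene named for GFP or Cre, and 508 genes had no count. Symbols were matched to GENCODE gene models on the same build for the positions given.

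Wells with at least 1000 counts, at least 500 genes and at most 20% mitochondrial counts were kept: 318 of 319 in animal 1 and 335 of 339 in animal 2. The 5 wells left out had 26.7% to 94.2% mitochondrial counts. Kept wells held 35542100 counts in animal 1 and 42280920 in animal 2. Cells were clustered with leidenalg 0.10.2 (igraph 0.11.9) under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The steps were log counts per 10000, centring per animal, scaling per gene with clipping, and 20 principal components. A shared-neighbour graph with 15 neighbours was then split at Leiden resolution 1. The package scanpy 1.11.5 served for the doublet search and an alternative neighbour graph. Clustering used the 116 genes with a count in at least 5 cells from 16 marker lists fixed before the data were examined (152 genes, 140 in the table), so that all other genes were left for tests. A cluster took the name of a list when at least 3 of its markers were higher by at least 1 on the log2 scale and were seen in at least 10% of its cells. The list also had to have the highest mean log2 ratio of the 16 lists. It had to hold at least 1 of the 10 leading genes, with no other list holding more. The median depth of the cluster in each animal had to reach a set fraction of that animal's median. Otherwise the cluster stayed unnamed. The graph type, the numbers of components and neighbours and this naming rule were chosen after the data were seen. A first clustering with the neighbour graph of scanpy was replaced because it did not rerun stably, and its shares are given among the alternatives.

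Counts were summed per animal and class for each class with at least 10 cells in each animal, 6 of the 7 classes, and 13431 genes outside the marker lists passed filterByExpr. Each class was compared with the mean of the other classes in 1 edgeR 4.0.16 quasi-likelihood fit under R 4.3.3 with TMM scaling and animal as a block (5 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fold change is therefore against the geometric mean of the other classes, whereas the depth-scaled counts in the edgeR unit (CPM) given beside it are against their plain mean per animal, and CPM are means ± SD over n = 2 animals. The ± beside a log2 fold change is a standard error of the fit and not an SD over the animals. It is the absolute log2 fold change over the square root of the quasi-likelihood F statistic. CPM given with a class or gate test are scaled to the library total times its TMM factor. CPM of marker sums, of surface genes by class or animal, of the untested class, of gates over both animals and of the animals are scaled to the library total alone, so the same gene can differ between the 2. The 19 pathway lists (354 genes, 351 in the table, sharing none with the marker lists) were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists and classes. Cells were gated on Cd200 and Eng transcripts after each was thinned to 1000 counts, into Eng positive, Cd200 positive with no Eng, and neither, and compared the same way; Cd200 and Eng were left out of that test. Shares, surface gene levels, animals and cycling cells (at least 2 counts from the G2/M list after thinning to 1000 counts) were described per animal with no test, since the series holds 1 group.

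Genes were named by a rule fixed before the data were examined. Per class, it took the 10 highest and 10 lowest fold changes among genes past the threshold, changed the same way in both animals and at 50 CPM or more on average. It also took the surface genes seen in at least 5% of cells and up to 4 members of each pathway list past its threshold. Per gate contrast it took the 10 highest and 10 lowest, and between animals the 10 largest log2 ratios (pseudocount 1 CPM) among genes with at least 100 counts. Fold changes of named genes at 0 in one side are given as bounds against 3 counts over the group, or as CPM. These bounds take counts as independent, which amplified counts are not, so they are not firm limits. The tests were checked on simulated data with 200 genes changed. Each gene was drawn alone around 1 mean, with the classes fixed and the changes balanced up and down. The simulation held no clustering, gene correlation or median shift, so false calls in the real data may be more frequent. The class fits recovered 4% to 12% of the 4-fold and 0% to 1% of the 2-fold changes. Their false calls were 0 of 8, 2 of 9, 1 of 7, 0 of 9, 2 of 15 and 1 of 5 for classes 1 to 6. At this size many true differences of that size are missed. The planned gates gave 25 false of 137 calls for Cd200 against neither and 53 of 116 for Cd200 against Eng, so their counts carry many false calls. At 9000 counts per well Cd200 against neither gave 3 false of 26. No contrast with Eng was simulated at that depth.

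Other settings fixed before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no block, no filter on low counts, and thinned or split counts. For the clustering they were clustering on 1000 variable genes, resolutions of 0.5 and 1.5, minimums of 500 and 2000 counts and removal of Scrublet doublets. For the gates and lists they were unthinned gates, a second thinning seed, gates without Thy1 or Enpep cells, an estimated correlation and fry. Cycling cells were also counted at 1 or 3 G2/M counts, and each animal was taken alone. Added after the data were seen were thinning to 9000 counts (also with size factors and with no block), a gate on 10 or more counts, and genes with 5 or more counts in 5% of cells. Also added were removal of wells above 300000 counts, a fit of all 7 classes, gates without the pericyte-like class, list tests with size factors, and the scanpy graph. The closing section gives their effect.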

Results

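The data are RNA counts of single femur cells with present or past activity of the cathepsin K promoter, sorted from 1 group of 2 animals. Animal 1 gave 318 kept cells with a median of 101207 counts and 2185.5 genes, and animal 2 gave 335 kept cells with a median of 119126 counts and 2177 genes. Over both, kept cells ranged from 9767 to 675621 counts. With 1 group, the comparisons are between classes of cells within the animals, between cells gated on surface marker transcripts, and between the animals side by side. The series title names a periosteal stem cell that mediates intramembranous bone formation and fracture healing, and the comparisons describe which skeletal cell classes carry the reporter and which transcripts set them apart.

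The reporter-positive cells fell into 7 classes, 5 of which carried the markers of a named skeletal cell type. Chondrocyte-like cells (class 1) made up 26.1% [21.4% to 31.3%] of animal 1 and 28.96% [24.2% to 34.1%] of animal 2, with 40192 summed CPM of chondrocyte markers. Periosteal fibroblast-like cells (class 2) made up 25.5% [20.8% to 30.6%] and 25.4% [20.8% to 30.4%], with 27866 CPM of their markers. Tendon and ligament-like cells (class 4) made up 13.8% [10.2% to 18.1%] and 11.6% [8.41% to 15.6%], with 14610 CPM of their markers and 19707 CPM of periosteal fibroblast markers. Osteoblast-like cells (class 6) made up 4.40% [2.43% to 7.28%] and 4.18% [2.30% to 6.91%], with 11803 CPM of osteoblast and 11993 CPM of chondrocyte markers. Pericyte and smooth muscle-like cells (class 7) made up 4.09% [2.19% to 6.89%] and 1.19% [0.326% to 3.03%]. The unnamed class 3 made up 14.5% [10.8% to 18.8%] and 24.5% [19.97% to 29.4%]. It carried 9783 CPM of chondrocyte markers, 5414 CPM of periosteal fibroblast markers, 2886 CPM of synovial and articular markers and 2730.2 CPM of tendon markers. Against other cells, the synovial and articular list had the highest mean log2 ratio in class 3 (1.34). Of its 5 genes 2 were raised (Prg4 and Cytl1), short of the 3 needed for a name. The chondrocyte and periosteal fibroblast lists had mean ratios of -0.83 and -1.93 there, with 0 markers raised in each. The unnamed class 5 made up 11.6% [8.33% to 15.7%] and 4.18% [2.30% to 6.91%], with 19046 CPM of periosteal fibroblast and 2256 CPM of osteoblast markers, against 19707 CPM of the former in class 4 and 2482 CPM of the latter in class 1. The sums hide which markers were raised. Of 17 osteoblast markers 4 were raised in class 5 (Sp7, Alpl, Mmp13 and Runx2) and 1 in class 1 (Omd). The mean log2 ratios over that list were -0.29 and -1.18.

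The mean shares over n = 2 animals were 27.5% ± 2.02 (SD), 25.4% ± 0.0697, 19.5% ± 7.08, 12.7% ± 1.55, 7.91% ± 5.27, 4.29% ± 0.158 and 2.64% ± 2.05 for classes 1 to 7. The intervals of the 2 animals did not overlap for class 3 and class 5 and overlapped for the other 5; with animal and plate confounded no test was made. Markers of macrophages, neutrophils, erythroid, lymphoid and Schwann cells, megakaryocytes and skeletal muscle did not reach 5 counts in 5% of cells for any gene, and of the osteoclast and endothelial lists 1 gene each did. Shares depended on the clustering: with clusters on the 1000 most variable genes class 2 fell to 14.3% and class 1 to 19.6%, and at resolution 0.5 classes 4 and 5 fell into 1 cluster of 20.3%. On the variable genes class 5 rose to 12.95% and class 7 to 5.57%. With the scanpy graph class 3 fell to 11.6% and class 6 to 2.47%.

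**Figure D1:**
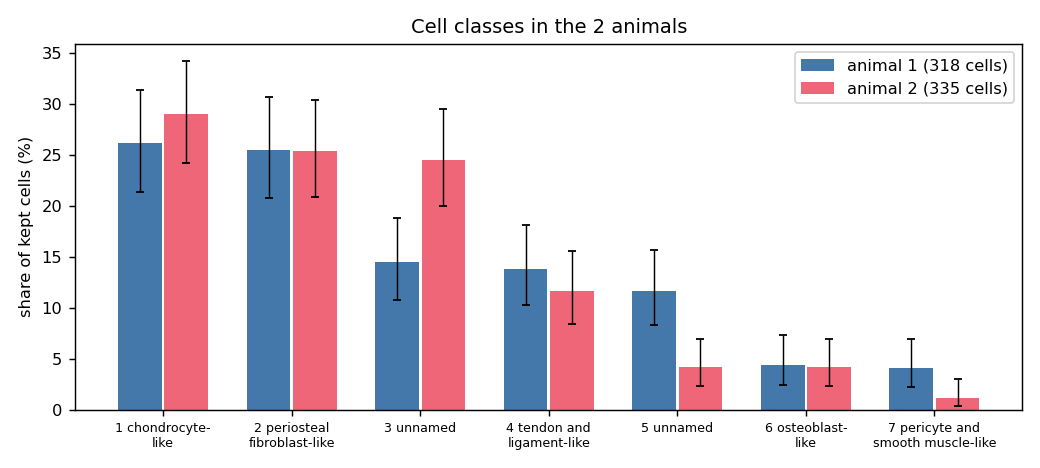
Share of kept cells (percent, vertical axis) in each of the 7 classes for animal 1 (318 cells, blue) and animal 2 (335 cells, red), with exact 95% binomial intervals as error bars. Class 3 was at 14.5% and 24.5% and class 5 at 11.6% and 4.18% in animals 1 and 2.

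Outside the marker genes, 94 genes differed between class 1 and the other classes (64 higher, 30 lower), 139 for class 2 (93 higher, 46 lower) and 11 for class 3 (10 higher, 1 lower). For class 4 there were 26 (26 higher, 0 lower), for class 5 13 (5 higher, 8 lower) and for class 6 94 (52 higher, 42 lower). Every one of these genes changed the same way in both animals. The fitted median over all 13431 genes was itself shifted, by 0.34, 0.38, 0.17, -0.000637, -0.11 and -0.23 on the log2 scale for classes 1 to 6 with TMM. With DESeq2 size factors the shifts were 0.20, 0.37, 0.13, 0.05, -0.06 and -0.12. Each fold change should be read against that shift. The DESeq2 Wald test gave 381, 540, 212, 389, 486 and 963 genes, of which 90, 139, 11, 26, 13 and 93 were among the edgeR calls.

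**Figure D2:**
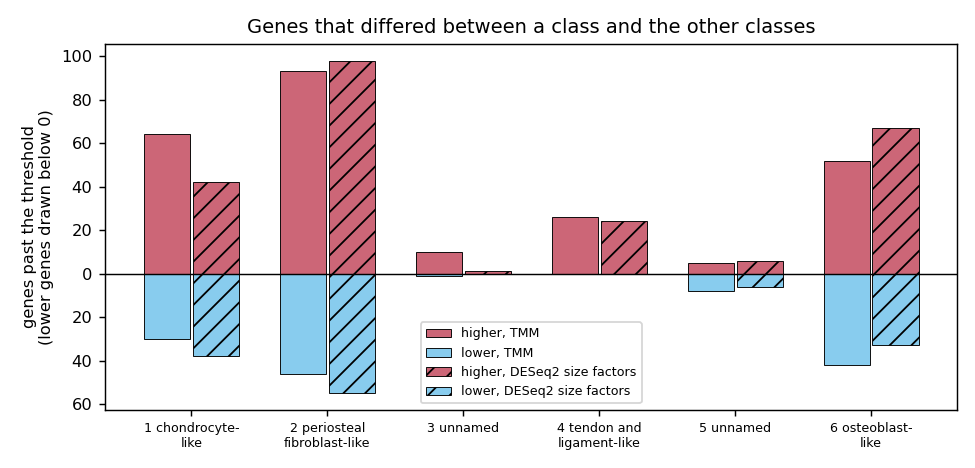
Number of genes outside the marker lists past the threshold (adjusted p below 0.05) in each tested class against the other classes, higher genes above 0 and lower genes below 0, with TMM (plain bars) and DESeq2 size factors (hatched bars). Class 2 had 139 genes with TMM and 153 with size factors, and class 3 had 11 and 1.

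Among the 64 genes higher in chondrocyte-like cells were the cartilage genes Mia, Scrg1, Col11a2 and Epyc. Mia, a small protein secreted by cartilage cells (ENSMUSG00000089661.9, chromosome 7, 27179742 to 27181157), was higher with log2 fold change 4.94 ± 0.45, adjusted p = 0.00587, 3759 ± 147 CPM against 379 ± 92.7 CPM. Scrg1, a secreted protein found in cartilage (ENSMUSG00000031610.3, chromosome 8, 57455923 to 57477585), was higher with log2 fold change 4.85 ± 0.39, adjusted p = 0.00424, 2252 ± 156 CPM against 384 ± 24.2 CPM. Col11a2, a chain of cartilage type XI collagen, was higher with log2 fold change 4.28 ± 0.31, adjusted p = 0.00383, 532 ± 159 CPM against 118 ± 16.3 CPM. Frzb, a secreted Wnt antagonist, was at 143 against 37.8 CPM, and Epyc, a cartilage proteoglycan, at 241 against 14.6 CPM, with 26.8% of all Epyc counts in 1 well. The co-chaperone Dnajb1 was higher by 3.02 ± 0.37 (adjusted p = 0.0190) and the long noncoding transcript A230065H16Rik by 3.96 ± 0.46 (adjusted p = 0.0161). Also past the threshold were Gpha2 (269 against 50.4 CPM, 23.2% of counts in 1 well), Fxyd3 (131 against 35.9 CPM, 24.6% in 1 well) and Msmp. For Msmp the mean was 54.96 against 100.4 CPM, since 1 well of class 3 held 73.7% of its counts.

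Among the 30 genes lower in the same cells were Ptn, Tmsb4x and Cd44. Ptn (pleiotrophin, a heparin-binding growth factor, ENSMUSG00000029838.11, chromosome 6, 36714929 to 36810220) was lower with log2 fold change -3.77 ± 0.37, adjusted p = 0.00830, 37.6 ± 1.92 CPM against 845 ± 53.2 CPM. Tmsb4x, an actin-sequestering peptide, was lower with log2 fold change -2.80 ± 0.27, adjusted p = 0.00804, 331 ± 42.8 CPM against 2769 ± 527 CPM. The hyaluronan receptor Cd44 was at 5.75 against 135 CPM (adjusted p = 0.0302). Igfbp6, which binds insulin-like growth factors, was at 4.88 against 397 CPM (adjusted p = 0.0190). The interferon-inducible Ifitm3 was at 31.2 against 828 CPM (adjusted p = 0.0262) and the phospholipid scramblase Ano6 at 1.76 against 63.03 CPM (adjusted p = 0.0137). Ptprd, Sfxn3 and Ddah2 were also lower, by log2 -3.71, -2.67 and -2.50. Ctsk itself was at 75.6 ± 1.40 CPM against 299 ± 50.5 CPM in these cells, with adjusted p = 0.0553, which did not pass.

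Of the pathway lists in class 1, matrix remodelling ranked below the other genes (adjusted p = 8.36e-08, and adjusted p = 0.145 with an estimated correlation). Of 17 genes 2 were lower, Mmp14 by -2.54 ± 0.36 and Mmp2, and 6 were lower adjusted over the list alone. Collagen matrix also ranked lower (adjusted p = 4.34e-07, and adjusted p = 0.196 with an estimated correlation). Of its 26 genes 6 were lower (Lox -1.82, Col1a1 -0.81, Col1a2 -0.48) and 1 higher (Mgp, an inhibitor of mineralisation, 1.48), or 12 and 4 adjusted over the list alone. The dissociation and immediate-early list ranked higher (adjusted p = 0.000243, and adjusted p = 0.434 with an estimated correlation). Of its 21 genes 4 were higher (Dnajb1, Zfp36 1.58, Ier2 1.52, Fos 0.88), or 14 adjusted over the list alone, and genes of this list respond to tissue digestion. Glycolysis and hypoxia ranked higher (adjusted p = 0.00247, and adjusted p = 0.328 with an estimated correlation), with 1 of 20 genes higher (Eno1, 1.49), or 4 adjusted over the list alone. Cholesterol synthesis ranked higher (adjusted p = 1.73e-05, and adjusted p = 0.196 with an estimated correlation) with 0 of 15 genes past the threshold, also adjusted over the list alone, and a median of 1.42. Interferon and antigen presentation ranked lower (adjusted p = 0.000583, and adjusted p = 0.262 with an estimated correlation), with 1 of 11 genes lower, or 2 adjusted over the list alone. Surface and lineage genes ranked lower (adjusted p = 0.00166, and adjusted p = 0.196 with an estimated correlation), with 1 of 21 lower, or 4 adjusted over the list alone.

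Growth factor signalling (FGF, PDGF and IGF) in class 1 ranked lower (adjusted p = 0.00328, and adjusted p = 0.196 with an estimated correlation) although its median was 0.26 and its mean -1.02. Igfbp5 (-2.22) and Igfbp6 were lower and Igf2 (0.66) higher, or 5 and 2 of 23 adjusted over the list alone. Ribosomal proteins passed with TMM (adjusted p = 0.0444, and adjusted p = 0.734 with an estimated correlation) with a median of 0.34, that of all genes. They did not pass with size factors (adjusted p = 0.239). Of the 26 genes 1 was higher (Rpl11, 0.41), or 24 adjusted over the list alone. With size factors, 80 genes differed (42 higher, 38 lower), 72 of them the same genes, and the count ranged from 80 to 381 over all alternatives. Of the 32 called genes that the naming rule took, 16 kept their call under every alternative that tested them. Col1a1, Lox, Mmp2 and Rpl11 lost it without the animal block, and Col1a2 was at 0.17 in a fit of all 7 classes.

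Among the 93 genes higher in periosteal fibroblast-like cells were those of the surface antigens Cd34, Ly6a and Ly6c1. Cd34, a surface sialomucin (ENSMUSG00000016494.9, chromosome 1, 194938819 to 194961279), was higher with log2 fold change 7.36 ± 0.60, adjusted p = 0.00223, 685 ± 148 CPM against 10.03 ± 1.71 CPM. Ly6a, the stem cell antigen Sca-1 (ENSMUSG00000075602.10, chromosome 15, 74994877 to 74998031), was higher with log2 fold change 6.98 ± 0.88, adjusted p = 0.0127, 1709 ± 468 CPM against 36.4 ± 17.4 CPM. Its relative Ly6c1 was at 876 against 18.8 CPM (log2 fold change 7.10 ± 0.86, adjusted p = 0.0108). Igfbp6 was higher with log2 fold change 4.54 ± 0.35, adjusted p = 0.00169, 1154 ± 344 CPM against 167 ± 17.6 CPM. Serping1, the inhibitor of complement C1, was higher with log2 fold change 4.93 ± 0.65, adjusted p = 0.0146, 904 ± 61.2 CPM against 54.5 ± 3.49 CPM. The matricellular growth regulator Nov was at 422 against 108 CPM (adjusted p = 0.00419) and Tppp3 at 1955 against 193 CPM (adjusted p = 0.0146). The chemoattractant Rarres2 was at 748 against 67.4 CPM (adjusted p = 0.0240), the Wnt antagonist Sfrp4 at 158 against 43.00 CPM (adjusted p = 0.0194) and Spink2 at 297 against 34.1 CPM (adjusted p = 0.0108).

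Among the 46 genes lower in class 2 were the cartilage genes Chad, Mia, Col11a2 and Scrg1. Chad, a cartilage matrix protein that binds cells, was at 7.47 against 1385 CPM (log2 fold change -6.96 ± 0.87, adjusted p = 0.0125). Mia was at 5.46 against 1129 CPM (adjusted p = 0.0159), Col11a2 at 1.98 against 224 CPM (adjusted p = 0.00535) and Scrg1 at 12.1 against 832 CPM (adjusted p = 0.0215). The Wnt inhibitor Wif1 was at 23.4 against 1208 CPM (adjusted p = 0.0240), Fam180a at 18.5 against 470.3 CPM (adjusted p = 0.00352) and the transferrin receptor Tfrc at 10.2 against 208 CPM (adjusted p = 0.0137). Ooep (1.04 against 147 CPM), Gpha2 (0.146 against 104 CPM) and Cilp2 (0.475 against 84.02 CPM) were also lower. Thy1, an antigen used to exclude cells from skeletal stem cell gates, was at 109.7 against 16.9 CPM with adjusted p = 0.0701. Vcam1 and Pdgfra had adjusted p = 0.0698 and 0.119, and none of the 3 passed.

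In class 2 the surface and lineage list ranked higher (adjusted p = 0.0310, and adjusted p = 0.286 with an estimated correlation). Of its 21 genes 3 were higher (Cd34, Ly6a and Cd44, the last by 3.23 ± 0.36), or 10 adjusted over the list alone. Interferon and antigen presentation ranked higher (adjusted p = 0.0177, and adjusted p = 0.390 with an estimated correlation), with 2 of 11 genes higher (Ifitm3 2.42, Ifitm2 0.83), or 4 adjusted over the list alone. Glycolysis and hypoxia ranked lower (adjusted p = 0.00166, and adjusted p = 0.317 with an estimated correlation), with 1 of 20 genes lower (Pkm, -1.36), or 7 adjusted over the list alone. So did ribosomal proteins (adjusted p = 0.000200, and adjusted p = 0.561 with an estimated correlation), with 1 of 26 lower (Rplp0, -0.43), or 7 over the list alone. The secretory pathway also ranked lower (adjusted p = 0.000265, and adjusted p = 0.390 with an estimated correlation), with 1 of 21 lower (Ssr4, -0.93), or 8 over the list alone. The G2/M list ranked higher (adjusted p = 0.00367, and adjusted p = 0.602 with an estimated correlation) with 0 of 17 genes past the threshold, also over the list alone. The immediate-early list ranked lower (adjusted p = 0.00584, and adjusted p = 0.520 with an estimated correlation) with 0 of 21, or 3 lower and 1 higher over the list alone. The median of all genes was 0.38 here. Size factors gave 153 genes (98 higher, 55 lower) with all 139 among them, and over all alternatives the count ranged from 106 to 540. Of the 26 called genes that the naming rule took, 13 kept their call under every alternative that tested them, Cd34, Ly6a, Ly6c1, Igfbp6 and Chad among them, while Rplp0 was at 0.03 after thinning.

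The unnamed class 3 differed in 11 genes, among them Ndufa4l2 and Fam162a, which respond to low oxygen. 1500015O10Rik, which encodes the secreted peptide precursor augurin (ENSMUSG00000026051.8, chromosome 1, 43730602 to 43742578), was higher with log2 fold change 1.45 ± 0.08, adjusted p = 0.00178, 6445 ± 320.3 CPM against 3403 ± 57.3 CPM. Clu, the extracellular chaperone clusterin (ENSMUSG00000022037.15, chromosome 14, 65968483 to 65981547), was higher with log2 fold change 2.09 ± 0.22, adjusted p = 0.0262, 459 ± 36.3 CPM against 123 ± 11.7 CPM. The hypoxia-induced mitochondrial gene Ndufa4l2 was higher with log2 fold change 2.03 ± 0.22, adjusted p = 0.0262, 389 ± 31.5 CPM against 127 ± 11.3 CPM, and the hypoxia-responsive Fam162a was at 830.2 against 341 CPM (adjusted p = 0.0262). The muscle and cartilage gene Mustn1 was at 219.8 against 71.2 CPM (adjusted p = 0.0424) and Scrg1 at 996 against 635 CPM (adjusted p = 0.0346). The immediate-early gene Ier2 was at 1682 against 861 CPM (adjusted p = 0.0262) and the matrix proteoglycan Bgn at 4831 against 3049.9 CPM (adjusted p = 0.0262). Gm42418, which overlaps ribosomal RNA sequence, was at 18764 against 13819 CPM (adjusted p = 0.0262). Msmp was at 499.7 ± 699.7 CPM against 11.5 ± 12.01 CPM, with 73.7% of its counts in 1 well. An Msmp count was seen in 34.9% of wells of the quadrant of that well, against 0% to 3.66% in the other 7. Marcks, a substrate of protein kinase C, was the 1 lower gene (44.7 against 258 CPM, adjusted p = 0.0262).

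Glycolysis and hypoxia genes ranked higher in class 3 (adjusted p = 2.72e-07, and adjusted p = 0.196 with an estimated correlation). Of the list 0 of 20 genes passed over all genes, and 7 were higher adjusted over the list alone, among the named members Tpi1 (1.06), Bnip3 (1.78) and Ldha (0.64). The immediate-early list ranked higher (adjusted p = 0.00367, and adjusted p = 0.505 with an estimated correlation), with 1 of 21 genes higher, or 6 over the list alone. The hindlimb position list ranked higher (adjusted p = 0.0206, and adjusted p = 0.262 with an estimated correlation), with 0 of 14, or 1 over the list alone. Matrix remodelling ranked lower (adjusted p = 0.00882, and adjusted p = 0.224 with an estimated correlation; 0 of 17, also over the list alone). Against an all-gene median of 0.17, size factors left 1 of the 11 genes (1500015O10Rik), and that gene lost its call in a fit of all 7 classes. None of the 11 genes kept its call under every alternative, and the count ranged from 1 to 212. The median depth of class 3 (95030.5 counts) was below that of every tested class but class 4 (90275.8 counts).

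Among the 26 genes higher in tendon and ligament-like cells were Ctsk and genes of the extracellular matrix. Egfl6, an extracellular matrix protein with EGF repeats (ENSMUSG00000000402.2, chromosome X, 166523007 to 166585720), was higher with log2 fold change 6.31 ± 0.50, adjusted p = 0.00349, 345 ± 177 CPM against 12.4 ± 1.11 CPM. Angptl1, a secreted angiopoietin-like protein (ENSMUSG00000033544.6, chromosome 1, 156838562 to 156861078), was higher with log2 fold change 3.38 ± 0.28, adjusted p = 0.00475, 709.5 ± 246 CPM against 92.8 ± 14.7 CPM. Ctsk, the collagen-degrading protease whose promoter drives the reporter (ENSMUSG00000028111.4, chromosome 3, 95499256 to 95509362), was higher with log2 fold change 1.71 ± 0.24, adjusted p = 0.0491, 549 ± 3.49 CPM against 204 ± 51.5 CPM. The matricellular protein Spon2 was at 891 ± 72.9 CPM against 122 ± 20.02 CPM (adjusted p = 0.0211). Igfbp6 was at 678 against 262 CPM (adjusted p = 0.00911), Nov at 419.7 against 109 CPM (adjusted p = 0.0115) and Ptn at 1391 against 575 CPM (adjusted p = 0.00911). The matrix genes Mfap4 (721 against 102 CPM), Pamr1 (251 against 54.2 CPM), Cpxm2 (265 against 48.9 CPM) and Tgfbi (438 against 109 CPM) were higher too. In this class 0 genes were lower past the threshold (1174 genes had an unadjusted p below 0.05, and the DESeq2 Wald test called 206 lower).

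Collagen matrix genes ranked higher in class 4 (adjusted p = 2.36e-09, and adjusted p = 0.196 with an estimated correlation), with 6 of 26 genes higher, or 19 adjusted over the list alone, and none lower. The type I collagen chains Col1a1 and Col1a2 were higher by 1.06 ± 0.06 and 0.98 ± 0.06 (adjusted p = 0.00169 and 0.00169). The type VI chains Col6a3 and Col6a2 were higher by 1.86 ± 0.14 and 1.66 ± 0.19 (adjusted p = 0.00276 and 0.0211). Growth factor signalling ranked higher (adjusted p = 0.00466, and adjusted p = 0.196 with an estimated correlation), with 1 of 23 genes higher, or 10 over the list alone. Matrix remodelling ranked higher too (adjusted p = 0.0459, and adjusted p = 0.317 with an estimated correlation), with 1 of 17 higher (Mmp2, 1.31), or 5 higher and 1 lower over the list alone. It had adjusted p = 0.0506 without the block. The immediate-early list ranked lower (adjusted p = 0.000243, and adjusted p = 0.434 with an estimated correlation), with 0 of 21 genes past the threshold, or 6 lower over the list alone. Glycolysis and hypoxia (adjusted p = 0.0118, and adjusted p = 0.390 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0259, and adjusted p = 0.390 with an estimated correlation) also ranked lower. In both lists 0 genes passed, also over the list alone. Size factors gave 24 genes, 23 of them shared, and the count ranged from 11 to 389 over the alternatives. Of the 16 called genes that the naming rule took, 6 kept their call in all of them (Egfl6, Nov, Spon2, Igfbp6, Angptl1 and Col6a3), and Ctsk lost its call without the block and in a fit of all 7 classes.

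Over all classes, none of the 34 list calls held with an estimated correlation, size factors kept 32 and a fit without the block 33. By fry, which tests a list against no change and not against the other genes, 20 of the 34 passed. The lists of BMP and TGF-beta, Wnt, hedgehog and Notch signalling and of oxidative phosphorylation passed in none of the 6 classes.

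Ctsk transcripts were present in part of the reporter-positive cells. At least 1 Ctsk count was seen in 66.4% [60.9% to 71.5%] of cells of animal 1 and 54.3% [48.8% to 59.8%] of animal 2. After thinning to 1000 counts the shares were 16.04% [12.2% to 20.5%] and 12.2% [8.93% to 16.2%], at 239.8 and 167 CPM. By class, scaled to the library total alone, it was highest in tendon and ligament-like cells (519.8 ± 10.8 CPM) and class 5 (482 ± 103 CPM) and lowest among the tested classes in chondrocyte-like cells (70.3 ± 3.03 CPM). Acp5, another osteoclast transcript, had at least 1 count in 52.8% and 46.3% of cells but at least 5 in 5.35% and 4.48%, against 43.4% and 35.5% for Ctsk, so 1 count in a cell is weak evidence of expression. Of the leukocyte gene Ptprc, 1 and 0 wells had a count, and of the endothelial gene Pecam1 2 and 1.

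Cd200 (CD200, ENSMUSG00000022661.14, chromosome 16, 45382135 to 45409053) and Eng (endoglin, ENSMUSG00000026814.16, chromosome 2, 32646595 to 32682669) encode surface proteins by which skeletal stem and progenitor cells are sorted. After thinning to 1000 counts, Cd200 was seen in 10.4% [7.25% to 14.3%] and 8.96% [6.12% to 12.5%] of cells of animals 1 and 2, and Eng in 1.26% [0.344% to 3.19%] and 0.299% [0.00756% to 1.65%]. Cd200 stood at 191 and 116 CPM and Eng at 14.3 and 9.84 CPM. Cd200 was at 496 ± 205 CPM in osteoblast-like and 219 ± 65.1 CPM in chondrocyte-like cells, against 45.1 ± 35.7 CPM in periosteal fibroblast-like and 21.2 ± 29.6 CPM in tendon and ligament-like cells. In none of the 6 classes did it pass the class test. Eng was at 20.01 ± 7.09 CPM in periosteal fibroblast-like and 0.212 CPM in osteoblast-like cells. Thy1 stood at 40.4 and 39.4 CPM and Enpep at 8.64 and 7.14 CPM in animals 1 and 2, and Ly6a at 365 and 551 CPM. Thinned to 9000 counts, Ctsk, Cd200 and Eng were seen in 37.6%, 25.0% and 4.63% of cells on average. Acp5, most of whose positive cells had under 5 counts, was seen in more cells than Eng at both depths (2.83% and 2.39% at 1000, 11.01% and 6.27% against 5.97% and 3.28% at 9000). Acp5 was also among the raised markers of tendon and ligament-like cells, so part of its counts may be expression. The comparison therefore does not show that Eng counts are background. The gates take 1 thinned count as positive, so background counts are not excluded from them, in particular for Eng.

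**Figure D3:**
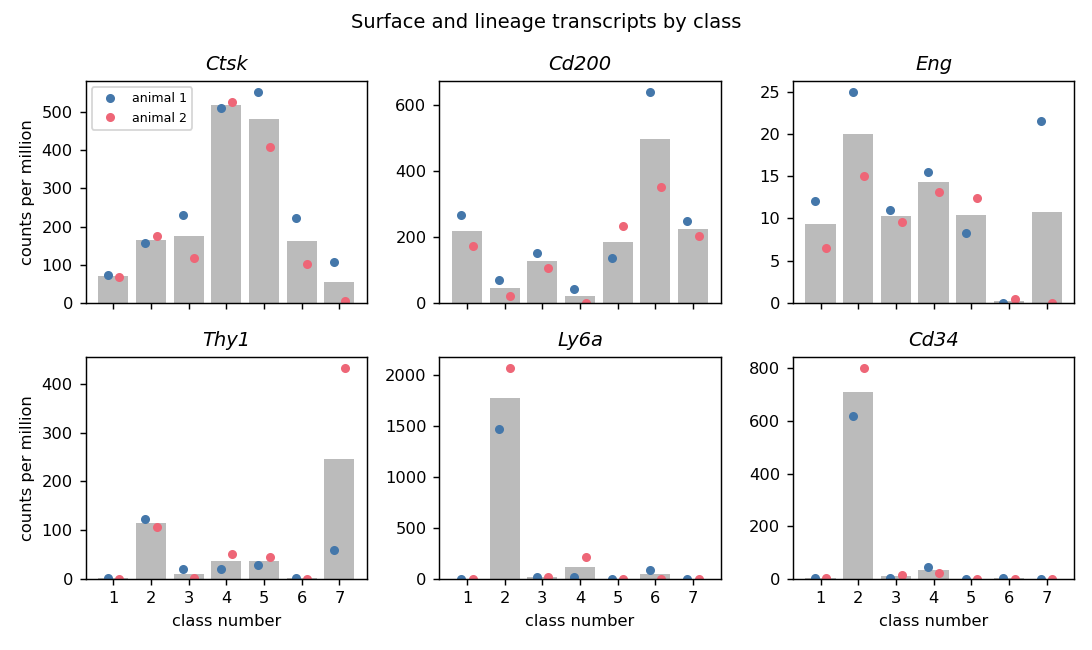
CPM, scaled to the library total alone, of 6 surface and lineage genes (vertical axes) in the 7 classes (horizontal axis), with bars for the mean of n = 2 animals and points for each animal. Ctsk was at 520 CPM in class 4 and 70.3 CPM in class 1, and Ly6a at 1772 CPM in class 2.

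Gating cells on these transcripts asked how Cd200-positive, Eng-positive and other cells of the reporter lineage differ. The planned gate, on cells thinned to 1000 counts, held 33 and 30 Cd200-positive cells with no Eng count in animals 1 and 2, 4 and 1 Eng-positive cells and 281 and 304 of neither. Of 680 genes, 188 differed between Cd200 and Eng cells (182 higher, 6 lower in Cd200 cells) and 125 between Cd200 cells and neither (5 higher, 120 lower). Between Eng cells and neither 421 differed (0 higher, 421 lower; the DESeq2 Wald test called 1 gene). These counts moved with the scaling and with the thinning seed. The fitted medians of all genes were 1.73, -0.60 and -2.34. With DESeq2 size factors they were 0.45, 0.10 and -0.41 and 1, 0 and 0 of 583 genes passed (90, 55 and 56 with an unadjusted p below 0.05). The DESeq2 Wald test gave 10, 1 and 1 genes, and a second thinning seed 61, 52 and 262.

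Under the planned setting 5 genes were higher in Cd200 cells than in cells of neither gate, and none of them passed with size factors or the DESeq2 Wald test. They were the mineralising-tissue sialoprotein Ibsp (1.92 ± 0.58, adjusted p = 0.0123), Spp1 (osteopontin, 1.08 ± 0.29, adjusted p = 0.00450) and Chad (0.92 ± 0.29, adjusted p = 0.0163). The others were Omd (osteomodulin, 0.88 ± 0.30, adjusted p = 0.0282) and the cartilage gene 3110079O15Rik (0.69 ± 0.22, adjusted p = 0.0154). Lower were Mfap5 (-4.15 ± 0.53, adjusted p = 2.42e-12), Tppp3, Thbs4 and Tagln2, and Kera, Ly6c1, S100a4, Nid1, Spon2 and Mt1, each of which had 1 to 3 counts in the Cd200 gate. The 10 named genes higher in Cd200 than in Eng cells all had 0 counts in the Eng gate, so they were at least 2.01-fold (Ier2) to 9.37-fold (3110079O15Rik) higher against a floor of 3 counts over the group. Plpp3, Mfap5 and Tmsb4x were lower in Cd200 than in Eng cells (-3.60 ± 1.25, -2.80 ± 0.96 and -1.63 ± 0.48), and Tmsb4x was higher by 1.57 with the second seed. Of the 4 Eng cells of animal 1, 2 were periosteal fibroblast-like, 1 tendon and ligament-like and 1 pericyte and smooth muscle-like. The 1 Eng cell of animal 2 was tendon and ligament-like, so none was chondrocyte-like or osteoblast-like. The 10 named genes lower in Eng cells than in neither were at 0 in the 5 Eng cells, at least 1.53-fold (Atp5j) to 4.05-fold (3110079O15Rik) lower. Under other settings the direction turned for 3 of them: 3110079O15Rik (0.0282) and Myl12a (0.16) at 9000 counts with size factors, and Ier2 (0.18) on unthinned counts.

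Thinning to 9000 counts, chosen after the results of the planned gate were seen, gave 82 and 71 Cd200 cells, 19 and 11 Eng cells and 217 and 253 of neither, with fitted medians of 0.37, -0.07 and -0.45 in the 3 contrasts. Of 7436 genes, 31 differed between Cd200 cells and neither (9 higher, 22 lower). Ibsp (ENSMUSG00000029306.8, chromosome 5, 104299171 to 104311469) was higher by 4.64 ± 0.71 (adjusted p = 0.00345, 670.3 against 36.2 CPM over both animals) and Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050) by 2.25 ± 0.45 (adjusted p = 0.0285). Chad was higher by 1.77 ± 0.26 (adjusted p = 0.00266) and the cartilage collagen Col2a1 by 1.11 ± 0.15 (adjusted p = 0.00228, 8532 against 3868 CPM). The microfibril genes Mfap5 and Fbn1 were lower by -2.20 ± 0.28 and -2.75 ± 0.40 (adjusted p = 0.00152 and 0.00266), the tendon gene Thbs4 by -2.66 ± 0.37 (adjusted p = 0.00228) and Ly6c1 by -3.82 ± 0.55 (adjusted p = 0.00266). Chad, Col2a1, Ly6c1, Fbn1 and Thbs4 passed with size factors and without the block as well, and Ibsp, Spp1 and Mfap5 with size factors only. On unthinned counts only Spp1 (adjusted p = 0.0456) of the 8 passed in this contrast. With the gate on 10 or more counts none did, and 0 genes passed by edgeR. There 378 of 14051 genes had an unadjusted p below 0.05, a share that is itself below 0.05. Each of the 8 kept its direction in both settings. Chondrocyte-like cells made up 43.9% and 40.8% of the Cd200 gate in animals 1 and 2 and osteoblast-like cells 13.4% and 18.3%, against 1.38% and 0.395% osteoblast-like and 19.4% and 26.1% chondrocyte-like cells in the gate of neither.

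Eng-positive cells at that depth had more Cxcl12, the chemokine of marrow stromal cells (ENSMUSG00000061353.11, chromosome 6, 117168535 to 117181367), with log2 fold change 3.08 ± 0.34 against neither (adjusted p = 0.000476, 907 against 81.3 CPM). It was the 1 gene higher of 13 that differed, and the 1 that passed with size factors (adjusted p = 1.33e-05) and without the block (adjusted p = 0.00238). The 12 lower genes passed in neither. Cxcl12 lost its call on unthinned counts (log2 fold change 2.60, adjusted p = 0.684) and with the gate on 10 or more counts (3.09, adjusted p = 0.483). Cd200 cells had less Cxcl12 than Eng cells (-2.43 ± 0.33, adjusted p = 0.00194), less Thbs4 (-2.65 ± 0.38, adjusted p = 0.00244) and less of the growth factor Igf1 (-1.94 ± 0.37, adjusted p = 0.0204). They had more Spp1 (3.10 ± 0.50, adjusted p = 0.00671) and Omd (2.21 ± 0.39, adjusted p = 0.0115). In this contrast 40 genes differed (31 higher, 9 lower; 23 and 17 with size factors), and 13 without the block. Without the block Spp1 (adjusted p = 0.180), Omd (adjusted p = 0.143) and Igf1 (adjusted p = 0.143) lost their calls, and Cxcl12 (adjusted p = 0.0123) and Thbs4 (adjusted p = 0.0267) kept theirs. On unthinned counts and with the gate on 10 or more counts 0 genes passed by edgeR (1260 of 14492 and 1576 of 14051 had an unadjusted p below 0.05). In the Eng gate Spp1 was at 689 CPM in animal 1 and 63.7 CPM in animal 2. Osteoblast-like cells made up 0% of the Eng gate in both animals, against 13.4% and 18.3% of the Cd200 gate. Periosteal fibroblast-like cells made up 26.3% and 45.5% of the Eng gate in animals 1 and 2. They made up 13.4% and 8.45% of the Cd200 gate and 29.95% and 29.2% of neither. Of Eng cells, 42.1% [20.3% to 66.5%] and 18.2% [2.28% to 51.8%] in animals 1 and 2 also had Cd200, against 27.4% and 21.9% of other cells, a difference not detectable at this depth.

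The 2 animals were close in abundant genes. Of 2568 genes with a mean of at least 50 CPM, 20 were 2-fold apart, and the SD of their log2 ratio was 0.33. Over 13215 genes with at least 100 counts, 1803 were 2-fold apart (1071 higher in animal 1, 732 in animal 2), or 2027 by the mean of cells. The correlation of log2 CPM was r = 0.942 and rho = 0.930 across genes, which are not independent replicates. The 10 genes furthest apart were mostly held by single wells, 6 of them with over 50% of their counts in 1 well. Il1rn, the interleukin-1 receptor antagonist, had 822 and 2 counts in animals 1 and 2 (ratio 489, counting interval 135 to 4044, 99.2% of counts in 1 well). Col10a1, the collagen of hypertrophic cartilage, had 756 and 2 (ratio 450 [124 to 3720], 99.1% in 1 well) and Msmp 138 and 5.27 CPM (73.7% in 1 well). Notch3, a receptor of mural cells, was lower in animal 2 by 3.63 on the log2 scale and Coch by 3.31, while Clic5 was higher by 3.56. For Notch3, 15.4% of counts were in 1 well, a pericyte and smooth muscle-like one. That class held 13 cells in animal 1 and 4 in animal 2, and its part in the Notch3 difference was not tested. Rab37 had 0 and 709 counts (at least 199-fold higher in animal 2 against a floor of 3 counts). Ptger3, Cnn1 and Bbs10 were at 0 in animal 2 (at least 125-, 123- and 123-fold higher in animal 1 against that floor). The counting intervals and the floor take counts as independent, which amplified counts are not, so they are not firm limits. Of the counts of Coch, Ptger3 and Cnn1, 73.7%, 71.1% and 73.9% were in 1 well each, so these differences rest largely on single wells.

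The share of cells with cycling transcripts depended on the depth at which they were counted. At least 2 counts of the G2/M list (17 genes, among them Mki67, Top2a and Cdk1) were seen in 5.97% [3.64% to 9.17%] of cells of animal 1 and 3.58% [1.86% to 6.17%] of animal 2, at 465 and 282 summed CPM. Periosteal fibroblast-like cells had 9.88% and 5.88%, tendon and ligament-like cells 4.55% and 5.13%, and class 3 2.17% and 6.10%. Chondrocyte-like cells had 6.02% and 0% (0 of 97 cells), class 5 5.41% and 0% (0 of 14), and osteoblast-like cells 0 of 14 in each animal. These zeros belong to the depth, since at 9000 counts 12 of the 97 chondrocyte-like cells, 1 of the 14 of class 5 and 2 and 4 of the osteoblast-like cells had 2 or more. Unthinned, the shares were 41.8% and 38.5%. Thinned to 9000 counts they were 14.2% and 17.3%, in the opposite order to the summed CPM. No order of animals or classes was therefore read from them, and cycling was not read from these shares alone.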

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

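The thinning to 9000 counts, the gate on 10 or more counts, the filter of 5 counts in 5% of cells, and the removal of wells above 300000 counts were chosen after the results were seen. So were the fit of all 7 classes, the gates without the pericyte-like class, the list tests with size factors and the scanpy graph. Of 118 calls of named class genes, 102 held with size factors, 117 with the DESeq2 Wald test, 93 without the block and 114 without the low-count filter. Without wells above 300000 counts 102 held, and in the fit of all 7 classes 77. Of 38 planned gate calls, 33 of those tested were lost with size factors, and 38 with the gate on 10 counts. On unthinned counts 36 were lost and 1 reversed, and 38 held without the pericyte-like class. Minimums of 500 and 2000 counts left every kept well in place and say nothing about stability. Split parts of amplified counts are not independent, class 6 could not be tested on them, and each animal alone leaves no residual degrees of freedom and was given no test. Depth and the few Eng-positive cells limit the gates. The 10 named genes lower in Eng cells had 0 counts in the 5 such cells at 1000 counts each. None of these cells was chondrocyte-like or osteoblast-like. For the cartilage genes among the 10, such as 3110079O15Rik and Mia, depth and class therefore cannot be told apart. Fmod, also among the 10, was a raised marker of tendon and ligament-like cells, a class that held Eng cells. For Fmod and the genes that are not of cartilage, the class of the cells does not account for the zeros, and depth was not excluded.

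The shares (percent) are those of the cluster with the highest Jaccard overlap with a class (cells in both over cells in either). For class 2 on variable genes that cluster held 48.2% of its cells. The causes of the moves below were not tested except where 2 classes shared a cluster. Clusters on 1000 variable genes gave 19.6 for class 1, 14.3 for class 2, 8.31 for class 4, 3.24 for class 6 and 5.57 for class 7, with classes 3 and 5 at 26.5 and 12.95, less than 1 SD from the reported means but above both animals. The scanpy graph gave 24.5 for class 1, 15.5 for class 2, 11.6 for class 3, 2.47 for class 6. At resolution 0.5 classes 4 and 5 merged into 1 cluster of 20.3 (98.8% and 98.0% of their cells), with 25.9 for class 2 and 2.47 for class 6, and resolution 1.5 gave 20.3 for class 2 and 3.24 for class 6. Without Scrublet doublets class 2 was at 21.6, and the cluster of 9.97 matched to class 6 (60.7% of its cells) was also that of class 5 (92.0%). Without wells above 300000 counts class 2 was at 21.9.

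Of the class counts, the DESeq2 Wald test gave 381, 540, 212, 389, 486 and 963 genes for classes 1 to 6, and thinning to 1000 counts 347, 249, 84, 82, 53 and 249. The filter of 5 counts in 5% of cells gave 177, 231, 34, 53, 49 and 150. The split counts gave 316, 312, 190, 80 and 136 for the clusters matched to classes 1 to 5. These clusters were made separately on the split counts. They held 66.1%, 46.99%, 85.2%, 87.95% and 76.5% of the cells of classes 1 to 5. Their gene counts are therefore not for the same groups of cells as the main calls. Without the block class 3 had 7 and class 4 had 11 genes, and with size factors class 3 had 1. The fit of all 7 classes gave 28, 42 and 57 for classes 3, 4 and 6, and removal of wells above 300000 counts 46 and 26 for classes 4 and 5. The stricter filter (6411 genes) and thinning (1078 genes) test fewer genes than the main fit (13431), which eases the adjustment. The DESeq2 Wald test left 2084 to 3385 genes per class out of its adjustment. The other causes were not tested.

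In the gates (Cd200 against Eng, Cd200 against neither, Eng against neither), size factors gave 1, 0 and 0 genes, the DESeq2 Wald test 10, 1 and 1, and no filter 47, 33 and 194. Unthinned counts gave 0, 1 and 0 of 14492 genes (1260, 493 and 1033 with an unadjusted p below 0.05). A second seed gave 61, 52 and 262, and 10 or more counts 0, 0 and 0 of 14051 genes (1576, 378 and 1443). For Cd200 against neither, 493 and 378 are shares below 0.05 of the genes tested. Thinning to 9000 counts gave 40, 31 and 13, with size factors 40, 38 and 1 and without the block 13, 8 and 1. Without the pericyte-like class Cd200 against Eng gave 116. The cause was not tested beyond the shift of the fitted median given with the gates.

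Values reversed for Col1a2 in class 1 with all 7 classes (0.17), Rplp0 in class 2 after thinning (0.0309) and Tmsb4x between Cd200 and Eng with the second seed (1.57). Values also reversed for 3110079O15Rik (0.0282) and Myl12a (0.16) between Eng and neither at 9000 counts with size factors, and Ier2 there on unthinned counts (0.18); the cause was not tested. With an estimated correlation 0 lists passed in each class, against 9, 7, 4, 6, 3 and 5, for reasons not tested. By fry, which tests against no change and not against other genes, 2 passed in class 3. At 9000 counts more cells had a count, by construction: Ctsk 37.6%, Cd200 25.0% and Eng 4.63%. Cycling shares were 9.08% of all cells with 1 or more counts and 15.7% at 9000 counts. By class, 9000 counts gave 14.6%, 20.5%, 14.1% and 12.4% for classes 1 to 4, 1 or more counts 11.5% for class 2 and 10.8% for class 4, and 3 or more counts 1.22% for class 3 and 0% for class 4.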

Other observations

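The tests on low counts across wells, the test of Hbb-bs shares over all 4 quadrants and the test of Tnni2 by quadrant and barcode were chosen after the result was seen; the other tests of this part were written before. Osteoblast-like cells (class 6, 14 cells in each animal) had 52 genes higher and 42 lower, and the highest median depth of the 7 classes (170122 counts). Spp1, the bone matrix protein osteopontin, was higher with log2 fold change 4.07 ± 0.45, adjusted p = 0.0151, 6205 ± 512 CPM against 609 ± 67.9 CPM. It was the 1 mineralisation gene of 8 tested past the threshold, in a list that ranked higher (adjusted p = 0.00192, and adjusted p = 0.196 with an estimated correlation). Car3, carbonic anhydrase 3, was higher with log2 fold change 11.30 ± 0.69, adjusted p = 0.000813, 964 ± 203 CPM against 1.66 ± 1.88 CPM, with 20.4% of its counts in 1 well. Sgms2, a sphingomyelin synthase of mineralising cells, was higher by 4.40 ± 0.37 (adjusted p = 0.00562). The channel protein Panx3 was at 319.9 against 21.8 CPM (adjusted p = 0.0311), the cartilage gene Chad at 2559.8 against 874 CPM (adjusted p = 0.0333) and Fxyd3 at 158 against 30.4 CPM. The secretory list ranked higher (adjusted p = 0.0173, and adjusted p = 0.487 with an estimated correlation), with 0 of 21 genes past the threshold, or 9 higher and 3 lower over the list alone. So did cholesterol synthesis (adjusted p = 0.00584, and adjusted p = 0.358 with an estimated correlation) and the immediate-early list (adjusted p = 0.0401, and adjusted p = 0.611 with an estimated correlation). In both 0 genes passed, also over the list alone. The G1/S list ranked lower (adjusted p = 0.00281, and adjusted p = 0.434 with an estimated correlation), with 0 of 16 genes past the threshold, or 4 lower over the list alone. Lower were Ptn (77.7 against 837 CPM, adjusted p = 0.0311), Angptl1, Nfib, Matn2, Zfp521 and Pxdn, and Egfl6 (0.203 against 81.4 CPM), Nov (0.865 against 192 CPM), Pamr1 (0.571 against 104 CPM) and Fbln5 (0.331 against 73.7 CPM). The median of all genes was -0.23 here, and size factors gave 67 higher and 33 lower of 100 genes. Of the 20 named genes 8 kept their call under every alternative that tested them, Spp1, Car3, Sgms2 and Chad among them.

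In class 5, 4 of 17 osteoblast and 3 of 16 periosteal fibroblast markers were higher, with mean log2 ratios over these lists of -0.29 and -0.31. The osteoclast list had the highest mean ratio there (0.206) with 0 of 9 markers higher, so the class stayed unnamed. Outside the marker lists 5 genes were higher, among them the secreted glutathione peroxidase Gpx3 (log2 fold change 3.29 ± 0.35, adjusted p = 0.0270, 1505 ± 390.1 CPM against 240.3 ± 0.303 CPM) and Ptn (log2 fold change 2.56 ± 0.24, adjusted p = 0.0212, 1453 ± 6.84 CPM against 562 ± 54.2 CPM). The other 3 were Thbs2 (934 against 424 CPM, adjusted p = 0.0270), the semaphorin co-receptor Nrp2 (147 against 48.9 CPM, adjusted p = 0.0372) and Ptprd (201 against 38.3 CPM, adjusted p = 0.0238). Thbs2 lost its call without the block and the other 4 in a fit of all 7 classes. Lower were Scrg1 (3.29 against 834 CPM, adjusted p = 0.0372), Col11a2 (1.42 against 224 CPM, adjusted p = 0.0267), Pcolce2 (0.318 against 136 CPM), Mustn1 (0.517 against 115 CPM), Sparcl1, Ndufa4l2, Cgref1 and Gm42418. Of the 13 named genes of class 5, 2 kept their call under every alternative that tested them (Scrg1 and Pcolce2). Matrix remodelling ranked higher (adjusted p = 0.0209, and adjusted p = 0.262 with an estimated correlation), with 0 of 17 genes past the threshold, or 4 higher over the list alone. The immediate-early list (adjusted p = 0.0392, and adjusted p = 0.611 with an estimated correlation) and glycolysis and hypoxia (adjusted p = 0.0480, and adjusted p = 0.434 with an estimated correlation, and adjusted p = 0.0554 with size factors) ranked lower. In these 2 lists 0 genes passed, or 7 and 1 lower over the list alone. The pericyte and smooth muscle-like class, with 13 and 4 cells, was not tested. Its contractile markers Acta2 and Rgs5 stood at 9796 and 4979 CPM against 48.6 and 40.7 CPM in other cells, and Tinagl1, outside the marker lists, at 773 against 0.105 CPM.

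Low counts of a gene appeared in many wells that otherwise lacked it. Well barcodes repeat between quadrants, so a quadrant was taken as 1 pool, and passing of sequences between its wells was set against free RNA in the suspension. Among 336 genes with at least 50 counts in 1 well and under 5 elsewhere, wells with 1 to 3 counts made up 0.443% of the same quadrant and 0.227% of the others, a ratio of 1.96, and 3 narrower definitions gave 5.45 (24 genes), 6.05 (23 genes) and 25.5 (3 genes, the first one run). Free RNA would give like shares in all quadrants and passing between wells a ratio of at least 2 under each definition, so 1.96 lies between the bounds and both may contribute. Wells with the same barcode in other quadrants stood higher still over the other wells there (1.16% against 0.239%, a ratio of 4.83, and 24.6, 27.05 and 89.9 under the narrower definitions), which neither explanation gives, and no biological explanation was tested, since the series holds 1 group.

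Hbb-bs, a beta-globin, had a count in 41.2% [35.7% to 46.8%] of wells of animal 1 and 3.88% [2.08% to 6.54%] of animal 2, and 95.4% of those wells of animal 1 had 3 counts or fewer. Spread over all wells of the plate would give like shares in all classes, and the highest class share was 1.73 times the lowest, within the bound of 2. Yet quadrant 4 of the plate had 3.66% [0.761% to 10.3%] against 46.2% to 59.3% in the other 3, which argues against a source common to all 4 quadrants. A source in 1 quadrant pool needed 1 quadrant to stand over 2 times above every other, but the ratio of the highest to the next was 1.04, which argues against it. An event that reached 3 of the 4 quadrants may remain, found after the fact and untested, and no biological explanation was tested.

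S100a9, a neutrophil gene, had a count in 63.4% of wells of quadrant 4 of animal 2 and 34.1% of quadrant 4 of animal 1, and in 3.85% or fewer of the other 6 quadrants. These counts were low. At least 5 S100a9 counts were seen in 1 of 318 kept wells of animal 1 and 2 of 335 of animal 2.

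Tnni2, a troponin of fast skeletal muscle, had at least 10 counts in 9 of 28 osteoblast-like wells (32.1% [15.9% to 52.4%]) and 22 of 625 others (3.52% [2.22% to 5.28%]). In the 31 such wells the summed counts of the more abundant muscle genes Acta1, Mylpf and Tnnt3 were 0.0185 times those of Tnni2 (121 against 6556 counts), which argues against muscle cells or their RNA. The 3 highest wells of the class held 88.6% of its Tnni2 counts, which carry-over from a few wells and expression in a few cells would both give. Carry-over from the 3 highest wells of all within their quadrants or barcodes would leave no other well of the class with 10 or more counts elsewhere, but 5 of 7 such wells (71.4% [29.0% to 96.3%]) shared neither with them, which argues against that route. Carry-over by another route and expression in some osteoblast-like cells may each remain; neither was tested, and Tnni2 was itself among the clustering genes.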
